A study of Mus musculus with 128 samples.

How the data were processed

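The series used v6.5 mouse embryonic stem cells, and its design text names a CRISPR screen for regulators of MagohB expression. The screen used Cas9 cells of 2 genotypes, wild type (WT) and knockout of Mll2 (gene symbol Kmt2b, an H3K4 methyltransferase), and the Brie library, a genome-wide mouse library of single guide RNAs (sgRNAs). For each genotype there was 1 library of the total population and 1 of a sorted population. The labels do not say which gate was sorted, so a higher share in the sorted population is given below without a direction of MagohB expression. The other samples of the 128 in the series (ChIP-seq, RNA-seq, PRO-seq and bisulfite sequencing) were not analysed here.

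The authors deposited raw read counts per sgRNA. Reads were aligned to the sgRNA sequences with Bowtie1, per the labels' protocols, and the submitters' processing notes list Bowtie 0.12.9, bcl2fastq 2.17 and Trimmomatic 0.33, with no role given. The counting tool is not given in the sources used here. Each file held 78634 lines with an ID, of which 1 was a leftover header with a count of 0, and the other 78633 sgRNAs of 19674 genes were analysed. The gene was taken from the sgRNA ID, since the gene column differed from it for 104 sgRNAs, among them names turned into dates. The files held 0 sgRNAs named as non-targeting controls. Of the gene names, 18645 matched a symbol in the RefSeq table of GRCm38.p6, which was used for names, synonyms and the chromosome of a gene; the files name no genome build and no coordinates are given.

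Deposited counts were divided by the library total to give CPM, counts scaled to the same library total. Sort enrichment was log2 of sorted CPM plus 1 over total CPM plus 1, for sgRNAs with at least 20 counts in the total population. The comparison of the total populations used the same ratio, Mll2KO over WT, for sgRNAs with a mean of at least 20 counts. sgRNAs were ranked, and robust rank aggregation (alpha 0.25) gave a score for each gene with at least 2 sgRNAs in each direction. Its one-sided permutation p came from 2000000 random sets of as many sgRNAs, so that 5e-07 is the smallest p possible, with Benjamini-Hochberg adjustment over genes in each direction and a threshold of 0.05. A comparison of 1 library with another leaves edgeR's quasi-likelihood test no residual degrees of freedom. It was used, as a test added after the data were examined, for sorted against total populations over both genotypes, on counts summed per gene with genotype as a block (4 libraries, 3 coefficients, 1 residual degree of freedom); a difference between the genotypes counts as error in it. The p-values rest on the sgRNAs of a gene; they compare the libraries, not the conditions, and no difference has a replicate check. Errors are SDs over sgRNAs of a gene unless another unit is named. High or low abundance in a total population was tested in the same way on CPM, over sgRNAs with a count in at least 1 library, a test added after the data were examined.

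Gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. The rule named the 10 genes with the smallest p for enrichment in a sorted population if fewer than 10 passed, up to 5 that passed for depletion, and the 10 smallest p in each direction for the difference and the totals. It also named Kmt2b, Magohb, Magoh, Cxxc1, Dnmt1, Suz12, Setd1a and Setd1b, and members of the lists with the smallest p. Adjustment over a list alone does not correct over the 22 lists, so in each comparison some members can pass it by chance. Of the list entries, 17 were not analysed here, including 2 repeated under an older name. A list's median is given with its percentile among 10000 random lists of the same size, matched on abundance in the total population in 10 classes except where abundance itself was compared; it describes these libraries and is not a p-value. Olfactory receptor genes, which stem cells are not known to need, took the place of the planned non-targeting background.

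The test was checked on simulated data for 19663 genes with 50 changed genes per fold, in which sorted libraries were drawn as cells per sgRNA. In the simulated WT sort it recovered 20% of genes with a 4-fold and 80% with an 8-fold enrichment, and in the simulated Mll2KO sort 86% and 100%. For the difference it recovered 34% at 8-fold and 80% at 32-fold, for the totals 12% at 2-fold and 94% at 4-fold, and for low abundance in the WT total 6% at 0.5-fold and 64% at 0.25-fold. Unchanged genes called in these simulations numbered 2 in the WT sort, 4 in the Mll2KO sort, 2 in the difference, 1 in the totals and 5 in low abundance. The test blocked by genotype recovered 0% of genes enriched 8-fold in both sorts and 72% at 16-fold, with 0 unchanged genes called. In all simulations every sgRNA of a changed gene was given the full fold. Recovery of real genes may be lower where some sgRNAs cut poorly. Alternatives, some of them chosen after the data were examined, covered the pseudocount, the minimum count, alpha, the score, the scaling and the random sets; one of them ranked sgRNAs by edgeR's exact test with the dispersion of the olfactory receptor sgRNAs. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 were used.

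Depth differed between the libraries. Total counts were 56930119 (WT total), 34633026 (WT sorted), 48811568 (Mll2KO total) and 43780048 (Mll2KO sorted). The Mll2KO total library held 0% odd counts, against 49.6% in the WT total, so its reads appear to be counted in pairs and its true depth is lower than its total. A count of 0 allows up to 0.0527, 0.0866, 0.123 and 0.0685 CPM in these libraries in the same order (3 counts, with each read of the Mll2KO total taken as counted 2 times). These floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. The binomial intervals below treat the sgRNAs as a random sample. They measure neither counting error nor the spread between libraries.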

Results

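The screen asked which genes, when cut by Cas9, change the expression of MagohB, a core protein of the exon junction complex, in WT and in Mll2KO mouse embryonic stem cells. Each of the 4 conditions had 1 library, and the libraries held 34633026 to 56930119 counts. The total populations were even: 0.547% of sgRNAs (exact 95% binomial interval 0.496 to 0.601) had a count of 0 in WT and 0.563% (0.512 to 0.618) in Mll2KO, with Gini indices of 0.284 and 0.306. The sorted populations were not. A count of 0 was found for 44.7% of sgRNAs (44.4 to 45.1) in the WT sort and 13.5% (13.2 to 13.7) in the Mll2KO sort, the Gini indices were 0.727 and 0.493, and the top 1% of sgRNAs held 8.51% and 4.77% of counts, against 2.89% and 3.18% in the totals.

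**Figure D1:**
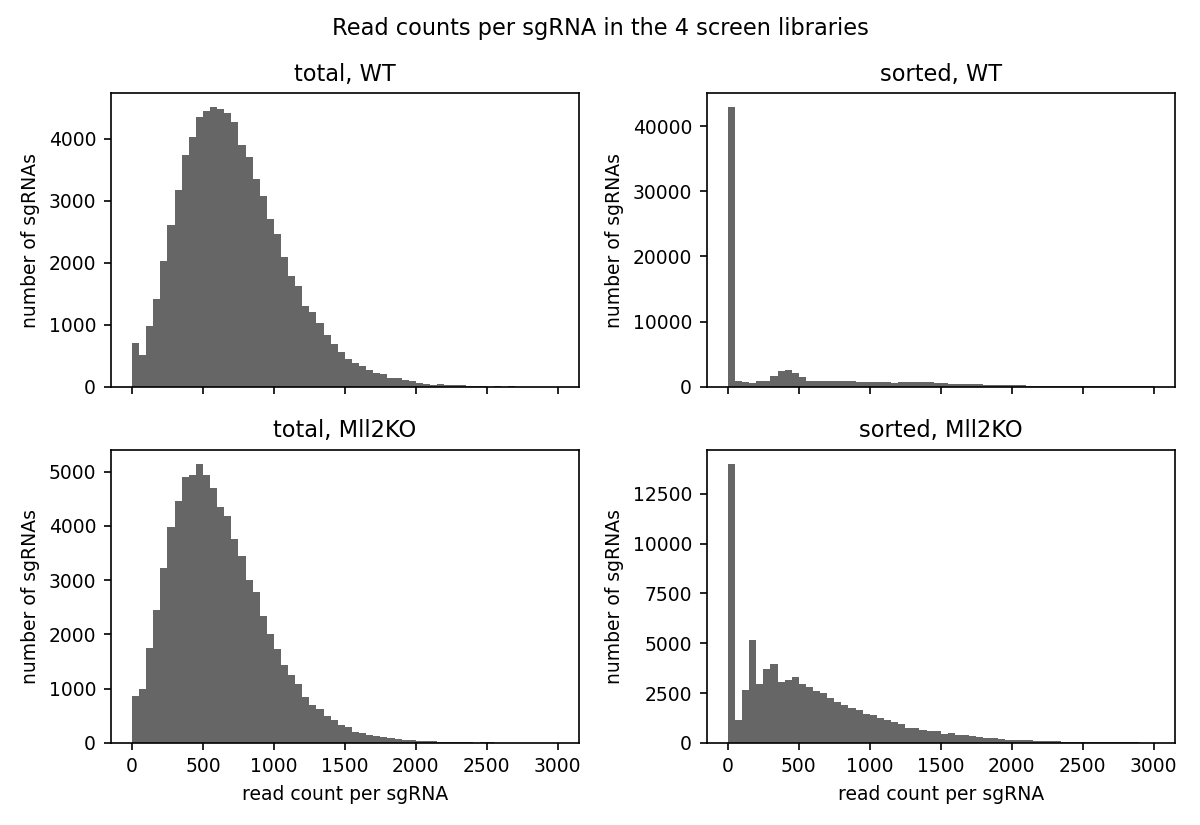
Number of sgRNAs (y axis, own scale per panel) by read count per sgRNA (x axis, bins of 50 counts, counts of 3000 and above not drawn) in the 4 libraries. The lowest bin, under 50 counts, holds 54.5% of sgRNAs in the WT sort and 17.8% in the Mll2KO sort, against 0.895% and 1.09% in the totals.

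In the WT sort, no gene passed the test for enrichment, and Trp53, which encodes the p53 tumour suppressor, passed for depletion as 1 gene of 19663, a call that most alternatives ended. The median count per sgRNA was 2 in this sort. For an sgRNA with 0 sorted counts, the ratio is set by its abundance in the total alone. Low medians here are therefore not sizes of a depletion, and a ratio above 0 partly marks an sgRNA that was recovered at all. The sgRNAs of Kmt2b, the gene deleted in the other genotype, were higher in the sorted population for 4 of 4 sgRNAs, with a median log2 ratio of 2.01 ± 1.01 against -1.79 for all genes, but Kmt2b did not pass over all genes (permutation p = 0.00354, adjusted p = 0.957). It did pass when adjusted over the list alone, both among the 6 MLL1/MLL2 COMPASS-like subunits and among the 8 genes fixed for the study. Magohb itself had a median of 1.58 ± 2.75 over 3 sgRNAs (permutation p = 0.0674), and its paralog Magoh 0.39 ± 2.41 (permutation p = 0.146).

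For Trp53, 2 of the 4 sgRNAs had 0 and 1 counts in the sorted population from 2195 and 2811 in the total, and the other two had 1142 from 1508 and 1568 from 2912. The median log2 ratio was -2.74 ± 3.20 and the adjusted permutation p 0.0393. With another draw of the random guide sets the adjusted permutation p was 0.0787, and over all alternatives it ran from 0.0197 to 0.991.

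The 10 genes with the smallest p for enrichment in WT did not pass. They were Ifnl2, with a median of 2.97 ± 2.92 and an adjusted permutation p of 0.324, then Surf1, Spaca3, Hsd17b7, Angpt1, Gsk3b, Nacc1, Zdhhc24, Slfn1 and Smim22, with adjusted p from 0.672 to 0.957. Gsk3b, a kinase of the WNT pathway, had 3 of 4 sgRNAs above 0 and a median of 2.69 ± 3.02. Zdhhc24 (1.79 ± 0.38) and Slfn1 (1.94 ± 0.43) had 4 of 4 sgRNAs above 0. At an unadjusted p under 0.05 there were 1008 genes for enrichment, where chance gives 983, and 1032 for depletion; edgeR's exact test called 0 in either direction. Among 1079 olfactory receptor genes, the background, none passed, and 5.28% had an unadjusted p under 0.05 for enrichment and 6.67% for depletion.

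Of the 22 gene lists, the list of DNA demethylation genes had the highest place in the WT sort. The median over its 4 genes was 0.50, at percentile 99.2 of random lists: Tet1 (0.73 ± 2.49) and Tet2, which oxidise methylated DNA, the glycosylase Tdg (0.26 ± 1.93) and the glycosyltransferase Ogt (-2.66 ± 2.18). Tet2 (2.17 ± 3.67, 3 of 4 sgRNAs above 0, permutation p = 0.00582) passed when adjusted over the list alone. Mbd2, a methyl-CpG binding protein, passed for depletion when adjusted over the list alone (-2.65 ± 2.89, 1 of 4 sgRNAs above 0, permutation p = 0.00176). PRC2, the H3K27 methyltransferase complex, had a median of -2.88 over 13 genes, at percentile 5.1, with 0 members past the test; Eed was at -4.25 ± 0.81 and Suz12 at 0.49 ± 2.64. The SET1 COMPASS subunits had a median of -2.23 (percentile 34.9), with Cxxc1 at -2.84 (0 of 4 sgRNAs above 0; -5.13 by the ratio of summed counts), Setd1a at -2.65 ± 2.32 and Setd1b at -1.37 ± 2.69. Wdr82, of the same list, was at 0.38 ± 2.73 with 2 of 4 sgRNAs above 0 (permutation p = 0.00976), and did not pass. Dnmt1, the maintenance DNA methyltransferase, was at -2.58 ± 1.17. For sgRNAs missing from the sort, such low values are set by abundance in the total. With 22 lists, chance puts 0.55 lists among the highest 2.5% of random lists. Members that passed when adjusted over a list alone numbered 2 for enrichment and 2 for depletion over the 22 lists. Without correction over the lists, such passes can come by chance.

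In the Mll2KO sort, Cpsf4, a subunit of the mRNA cleavage and polyadenylation machinery, passed for enrichment as 1 gene of 19663, and 0 genes passed for depletion. Its median log2 ratio was 2.52 ± 2.02, with 3 of 4 sgRNAs above 0, against -0.26 for all genes (adjusted permutation p = 0.0295). The sgRNAs of Cpsf4 were scarce in the Mll2KO total, with 20, 44, 228 and 512 counts. The adjusted permutation p was 0.859 with a minimum of 100 counts and 0.735 with halved Mll2KO total counts, in a range of 0.0197 to 0.859 over the alternatives. Kmt2b, already deleted in these cells, had a median of -0.85 ± 1.45, and Magohb of 0.44 ± 1.24 (permutation p = 0.0655).

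The next genes did not pass in the Mll2KO sort. Urod, an enzyme of haem synthesis, was above 0 for 4 of 4 sgRNAs with a median of 2.24 ± 0.52 and an adjusted permutation p of 0.275, and it passed when ranked within abundance bins (0.00983, the lowest of a range up to 0.56). Fam111a (1.46 ± 0.22, adjusted permutation p = 0.763) also passed within bins (0.0246, the lowest of a range up to 1). Chrdl2 (1.42 ± 0.71) and Gcm2 (2.02 ± 1.97) had the same adjusted p as Urod. Lpin2, Olfr1243, Ppp4r1, Ankmy1 and Cldn8 completed the 10, with adjusted p of 0.759 to 0.763. Olfr1243, at 1.41 ± 0.14, belongs to the background family. At an unadjusted p under 0.05 there were 1008 genes for enrichment and 1043 for depletion, where chance gives 983. Of the olfactory receptor genes none passed, and 5.65% and 4.17% had such a p.

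The SET1 COMPASS subunits, which form the main H3K4 trimethylation complex of mammalian cells, had a median of 0.62 over 6 genes in the Mll2KO sort, 0.89 above that of all genes and at percentile 99.5 of random lists. Over all genes 0 of them passed. Wdr82, with 4 of 4 sgRNAs above 0 at 1.11 ± 0.14 (permutation p = 0.000887), passed when adjusted over the list alone, and Setd1b (1.26 ± 2.99, permutation p = 0.0239) and Bod1 (0.75 ± 2.38, permutation p = 0.0292) did not. Setd1a was at 0.50 ± 0.32 and Cxxc1 at -1.37 ± 1.67. Supt6, an elongation factor, passed for enrichment when adjusted over the list alone (1.49 ± 1.98, 3 of 4 sgRNAs above 0), and Hcfc1 (-2.16 ± 0.66, 0 of 4) and the proteasome subunit Psmd3 (-1.40 ± 2.89, 1 of 4) for depletion. The lists below percentile 2.5 were the cytosolic ribosome (median -0.85 over 94 genes), Mediator (-0.69 over 30) and the p53 pathway (-0.82 over 14), each with 0 members past the test over all genes. The tests of single ribosome genes did not follow the low median, with 9 at an unadjusted p under 0.05 for enrichment and 5 for depletion. Dnmt1 was at -0.87 ± 0.91, Suz12 at -0.08 ± 0.71 and Magoh at -0.52 (1 of 4 sgRNAs above 0).

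**Figure D2:**
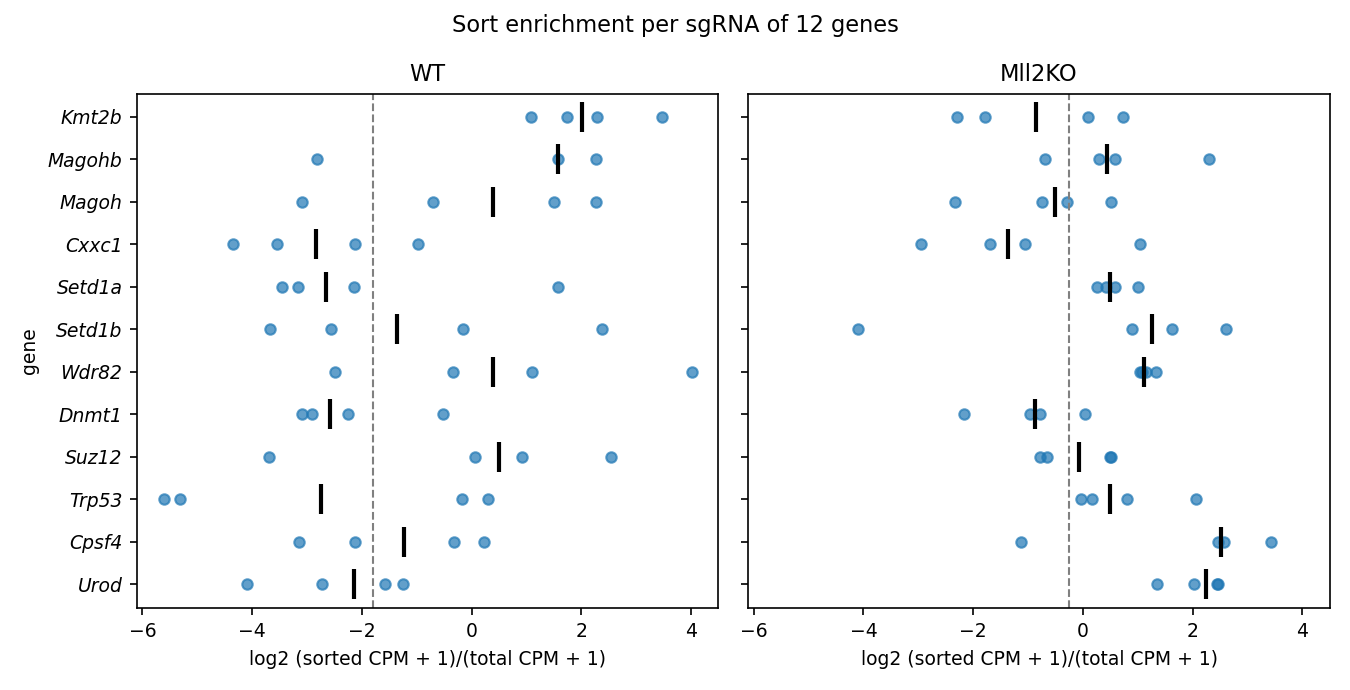
Log2 ratio of sorted to total CPM plus 1 (x axis) for each sgRNA (points) of 12 genes (y axis) in WT (left) and Mll2KO (right); black ticks are medians over sgRNAs with at least 20 counts in the total, and dashed lines the median of all genes (-1.79 and -0.26). All 4 Kmt2b sgRNAs lie above 0 in WT, with a median of 2.01, and the median is -0.85 in Mll2KO; neither passed over all genes.

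No gene passed the test of the difference in sort enrichment between Mll2KO and WT, and dividing the difference by its counting error called 1 gene, Urod, higher in Mll2KO (4.61 ± 1.52, permutation p = 0.0162 without that division). Kmt2b had 0 of 4 sgRNAs above 0 and a median difference of -2.53 ± 2.02, against 1.13 for all genes (permutation p = 0.00945, adjusted p = 0.937). Wdr82 differed by 0.80 ± 2.79 (permutation p = 0.604 for a higher value in Mll2KO), Tet2 by -2.57 ± 4.95 (permutation p = 0.00346, past the threshold only when adjusted over the list alone), Trp53 by 3.51 ± 2.87 (permutation p = 0.013) and Cpsf4 by 4.17 ± 3.13 (permutation p = 0.0572). The smallest adjusted p were 0.457 for a higher value in Mll2KO, shared by Pyroxd2, Rnf128, Olfr734, Wdr54, Asxl1 and Trmt10a, and 0.489 for a lower one, shared by Fosb, Ccser2, Chst5 and Clec1b. Rnf128 had 4 of 4 sgRNAs above 0 at 5.40 ± 0.60 (7.35 by the ratio of summed counts), and Asxl1, a Polycomb-associated protein, had 3 of 4 at 4.84 ± 3.35. Sipa1, Kap, Scarf2 and Siglece followed on the higher side (adjusted p = 0.492 by the permutation test), and Gucy2d, Psmd3, Lrrc59, Grik5, St6galnac2 and Cdpf1 on the lower side. Psmd3 passed there only when adjusted over the list alone, with a median of 0.95 ± 5.55 and 3 of 4 sgRNAs above 0. St6galnac2 was at -2.84 ± 0.48 (-4.09 by the ratio of summed counts) and Grik5 at -3.42 ± 1.14, each with 0 of 4 sgRNAs above 0. The SET1 COMPASS subunits had a median difference of 1.03, at percentile 45.9, and did not stand apart from random lists here. The cytosolic ribosome was the only list below percentile 2.5 (median 0.67, percentile 1.6). Of the olfactory receptor genes none passed, and 5.93% had an unadjusted p under 0.05 for a higher and 5.47% for a lower value in Mll2KO. The gates of the 2 sorts are not given, so this comparison also holds any difference between them.

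Over both genotypes, with genotype as a block, no gene passed for sorted against total populations by edgeR's quasi-likelihood test (smallest adjusted p = 0.929; 117 genes at an unadjusted p under 0.05, where chance gives 983). The log2 ratio was 1.49 for Magohb, 1.29 for Kmt2b, 1.34 for Wdr82, 1.09 for Tet2, -1.50 for Dnmt1 and -4.68 for Cxxc1, each at that adjusted p. The genes called in a single sort had small ratios here, -0.25 for Trp53 and 0.62 for Cpsf4, against a median of -0.19 for all genes. These ratios come from counts summed per gene, so they are not the same measure as the medians over sgRNAs of the single sorts. With 1 residual degree of freedom this test could show strong changes alone. With 0 genes called enriched in WT and 1 in Mll2KO, the overlap of the lists could not be tested at this threshold. Across genes, which are not independent replicates, the median log2 ratios of the 2 sorts had a Spearman correlation of 0.0552.

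In the total populations, sgRNAs against genes that every cell needs were scarce in both genotypes. The median log2 CPM of the cytosolic ribosome's sgRNAs lay 1.13 below that of the olfactory receptors in WT (2.68 ± 0.91 against 3.81, SD over 375 sgRNAs) and 1.17 below in Mll2KO (2.64 ± 1.00). Core splicing factors lay 1.04 and 1.11 below, and proteasome subunits 1.03 and 0.97. Each of these lists was at percentile 0 of random lists. Of 94 genes in the ribosome list, which also holds the Rps6k kinases through its naming pattern, 64 were low in WT and 44 in Mll2KO when adjusted over the list alone, and 7 and 5 over all genes; of 26 splicing genes 17 and 13 were low when adjusted over the list alone and 1 and 0 over all genes, and of 31 proteasome genes 14 and 5, and 2 and 0.

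The genes called low over all genes numbered 35 in WT and 12 in Mll2KO. In WT they included Rpl17 (log2 CPM 1.52 ± 0.38), Rpl10a (1.91 ± 0.17), the spliceosomal helicase Snrnp200 (2.10 ± 0.26), Orc6 (1.59 ± 0.49), Smn1 (1.63 ± 0.20), Mdm2, which restrains p53 (1.51 ± 0.84), and Usp7 (1.57 ± 0.33), with adjusted permutation p of 0.00492 to 0.0464. In Mll2KO they included Rpl15 (0.73 ± 0.76), Rpl17 (1.63 ± 0.26), the tubulin Tubg1 (1.41 ± 0.88) and the importin Kpnb1 (1.59 ± 0.93). Another draw of the random sets gave 7 genes in Mll2KO, without Kpnb1, and the median of the guides gave 0 genes in WT. Without the highest-ranked sgRNA there were 69 and 22, and with random sets of olfactory receptor sgRNAs 296 and 48. Genes called high numbered 5 in WT, namely Zfp296 (5.67 ± 0.36), Trp53 (5.48 ± 0.43), Actr5, Klhl3 and Ap2b1, and 2 in Mll2KO, namely Trp53 (5.65 ± 1.17) and Gm20852 (5.30 ± 0.90). Without each gene's highest-ranked sgRNA both Mll2KO calls ended (adjusted permutation p = 0.059 for each), as did that of Ap2b1 in WT (0.061), and with random sets of olfactory receptor sgRNAs those of Actr5, Klhl3 (0.101 for each) and Ap2b1 (0.165) ended in WT. The plasmid pool was not analysed here, so the starting abundance of the sgRNAs is unknown. Some low genes (Hist1h3h, Vmn2r31, Gm3558) belong to families of near-identical copies, whose sgRNAs may cut at several sites and share reads. Of the olfactory receptor genes none passed, and 10.6% in WT and 8.62% in Mll2KO had an unadjusted p under 0.05 for high abundance and 2.04% and 2.97% for low abundance.

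**Figure D3:**
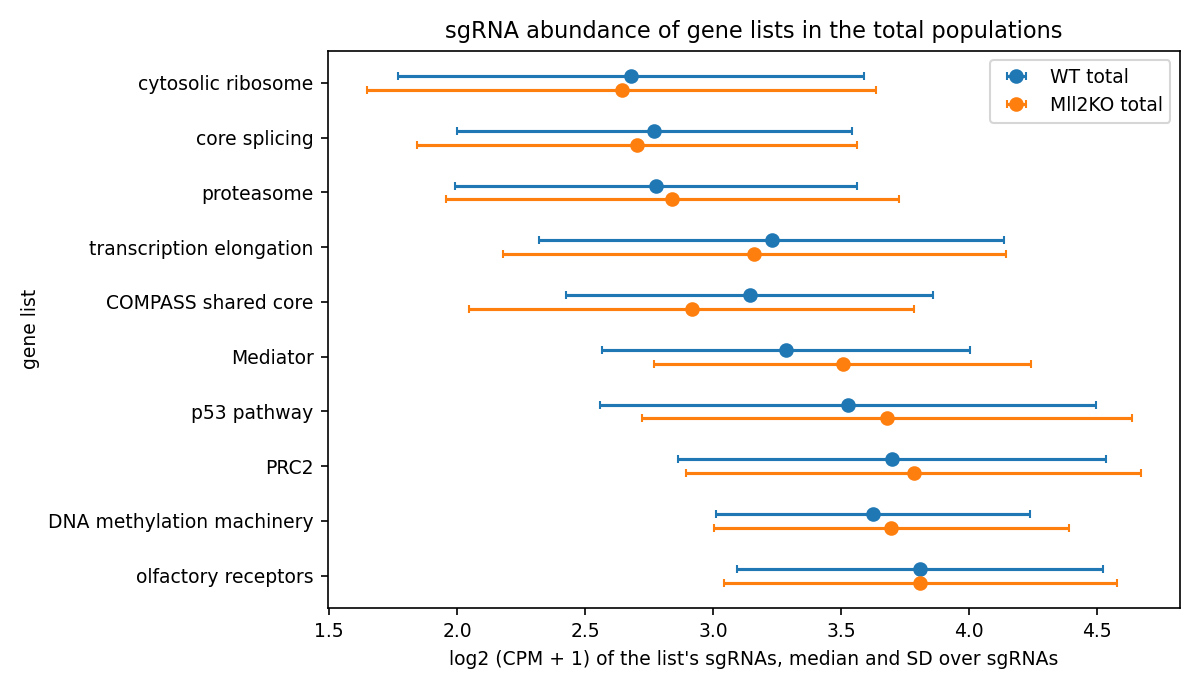
Median log2 (CPM + 1) of the sgRNAs of 10 gene lists (points; bars are SDs over sgRNAs) in the WT and Mll2KO total populations, with 1 library each. The cytosolic ribosome lies at 2.68 and 2.64 and the olfactory receptors at 3.81 in both.

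Between the total populations, the 3 genes that passed were of chromosome Y. sgRNAs of Sly, a spermatid gene of a multicopy family, were higher in Mll2KO by 2.03 ± 0.55 on the log2 scale, those of Gm20867 by 2.31 ± 1.02 and those of Gm20831 by 1.67 ± 0.66, each for 4 of 4 sgRNAs (adjusted permutation p = 0.0229 for each). They were the 3 genes called higher, and 0 were called lower. Near-identical copies can share reads, so the split between members of these families is uncertain. Each call was lost under some alternative: Gm20867 and Sly with a pseudocount of 5 CPM (adjusted permutation p = 0.0639 and 0.095), and Gm20831 by the median of the guides (0.167), which called Rhot2 (0.00655).

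**Figure D4:**
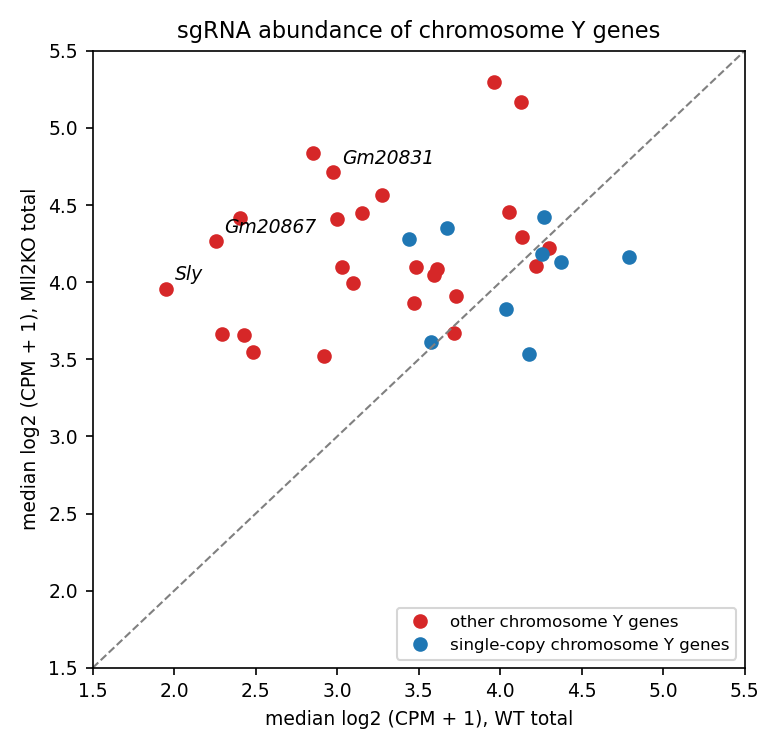
Median log2 (CPM + 1) over the sgRNAs of each of 35 chromosome Y genes (points) in the WT total (x axis) and the Mll2KO total (y axis), with 1 library each; the dashed line marks equal values. The 9 single-copy genes lie on both sides of the line, while Sly lies at 1.95 in WT and 3.96 in Mll2KO.

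Rhot2 (1.94 ± 1.75), Zbtb9, Gm20816, Radil, Olfr114, Smn1 (1.31 ± 0.62) and Rsl1d1 followed without passing. On the lower side P2ry14, Sipa1, Slc7a5 (-1.26 ± 0.67), Zc3h7b, Gm10406, Polr3gl, Lrrc10, Rpl15 (-1.54 ± 0.47), Hist1h3i and Klrc2 had the smallest p, all with an adjusted permutation p of 0.758. Of the genes fixed for the study, Dnmt1 (0.53 ± 1.37, 4 of 4 sgRNAs above 0, permutation p = 0.00343) and Magoh (0.04 ± 1.43, 2 of 4, permutation p = 0.00762) passed for a higher value when adjusted over the list alone and did not pass over all genes; the median of Magoh was near 0. Among the lists, Ssrp1 (1.81 ± 1.45, 2 of 3 sgRNAs above 0) and Psmd3 (0.22 ± 2.09, 2 of 4) passed in the same way for a higher value, and Dpy30 (-0.69 ± 1.07, 2 of 4) and Rpl15 (0 of 3) for a lower one. Kmt2b differed by 0.45 ± 1.07, Magohb by -0.47 ± 0.45, Cxxc1 by -0.51 ± 1.19, Suz12 by 0.40 ± 0.98, Setd1a by -0.12 ± 0.69 and Setd1b by 0.16 ± 0.79. The growth-restraining genes of the PI3K-mTOR, RAS and Hippo pathways had a median of 0.22 over 19 genes, at percentile 98.6, with 0 members past the test.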

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

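Alternatives with olfactory receptor guides, abundance bins, sorted counts under 50 set to 0, halved counts, another draw, unadjusted overlap and every alternative of the abundance tests were chosen after seeing the data. For each sort alone, their difference and the totals, no paired analysis was possible because each condition has 1 library; for the same reason no library could be left out in turn. The sort effect over both genotypes, a test also added after seeing the data, could be blocked by genotype: edgeR's quasi-likelihood test called 0 genes, 0 with TMM and 0 with sgRNAs ranked by it. Alternatives that need non-targeting guides were not run, since the files name none. Size factors shifted the median log2 ratio of all guides by -0.15 in the WT sort and 0.11 in the difference. Of 293 comparisons of counts or lists with an alternative, 255 stayed, and of 1684 for named genes 1585 did. A count stayed if it was equal or near, and a list's abundance if it moved by less than the SD over sgRNAs. A gene stayed if it kept its side and remained called or uncalled, or moved by less than its SD by summed counts. Many genes were called under neither setting, so these numbers do not measure how firm the calls are. The calls of the sorts and the totals were each lost under some alternative. The cause of a change was not tested except where stated.

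In the WT sort 0 genes were called depleted, and 0 list members, with a pseudocount of 5 CPM, no minimum, a minimum of 100 counts, without each gene's highest-ranked guide, by the median, by edgeR's exact test, with olfactory receptor sets, within abundance bins, with sorted counts under 50 set to 0 and with another draw; adjusted p for Trp53 ran from 0.0197 to 0.991. In the Mll2KO sort 0 genes were called enriched with 5 CPM, with a minimum of 100 counts and with halved Mll2KO total counts, which takes 1 Cpsf4 guide under the minimum, and 2 (Urod and Fam111a) within bins. For the difference, dividing by the counting error called 1 gene, Urod. For the totals, 5 CPM left 1 gene, Gm20831; Gm20867 was also lost with 0.1 CPM and by edgeR's exact test, and the median called Rhot2 in place of Gm20831. Shared enriched genes were 87 at an unadjusted p under 0.05 and 73 within bins.

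For low abundance, leaving out the highest-ranked guide gave 69 genes in WT and 22 in Mll2KO, the median 0 and 3, olfactory receptor sets 296 and 48, and alpha 0.05 and another draw 7 each in Mll2KO. For high abundance, olfactory receptor sets gave 2 genes in WT and leaving out the highest-ranked guide 0 in Mll2KO.

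The side with the smaller p changed for genes that passed under neither setting. By the ratio of summed counts Angpt1 (3.45), Lpin2 (2.10) and Lrrc10 (-2.25) had the other sign, and Cxxc1 (-5.13 in the WT sort, 5.25 in the difference), Rnf128 (7.35), Trmt10a (7.43), Scarf2 (3.36) and St6galnac2 (-4.09) moved by more than the SD over their sgRNAs. Sorts: Setd1a -2.65 (median) and Setd1b -1.37 (bins) in WT, Cxxc1 -0.55 (5 CPM), Setd1b 0.89 (minimum 100) and Lpin2 -2.17 (without highest guide, and median) in Mll2KO. Difference: Suz12 0.44 (minimum 100, and halved counts) and -0.63 (counting error), Sipa1 1.17 (without highest guide, and counting error), Cxxc1 0.52 and Setd1b 0.65 (median), Kap 2.21 and Chst5 -1.40 (counting error). Totals: Suz12 0.32 (5 CPM) and 0.40 (median), Magohb -0.10 (no minimum), Lrrc10 0.33, Kmt2b 0.45 and Cxxc1 -0.51 (without highest guide, and median; Kmt2b also in bins) and Setd1b 0.16 (median). Abundance: Kmt2b 3.38 (median, and olfactory receptor sets), Dnmt1 3.78 and Suz12 3.75 (median) in WT, Suz12 4.24 (without highest guide, and median), Kmt2b 3.82 (median) and Setd1a 3.59 (median, and olfactory receptor sets) in Mll2KO.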

Other observations

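The split of chromosome Y into single-copy and other genes, and the tests of missing sgRNAs by abundance, of the doubled counts and of repeated Y copies, were chosen after the results were seen; the tests of depth, of missing sgRNAs per gene, of matched genes off chromosome Y and of abundance bins were written before their results.

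Chromosome Y stood apart in the comparison of the total populations. Its 35 genes had a median difference of 0.61 on the log2 scale, Mll2KO minus WT, while the X chromosome's 790 genes had -0.01. The 9 single-copy genes, such as Uty, Zfy1, Kdm5d and Ddx3y, had a median of 0.08 ± 0.32 (SD over genes). The other 26, among them Sly and Ssty1 (1.47 ± 1.16 over its sgRNAs) and many predicted genes, had a median of 0.97 ± 0.64. Of these, 18 had an unadjusted permutation p under 0.05. Near-identical copies may share reads and sites to cut, so the 26 genes are not independent. Their SD and the count of 18 describe the set and do not measure replicates. The set also holds the genes called higher between the total populations, and was split off after those calls were seen.

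A general loss of cutting or a shorter culture of the Mll2KO cells would raise other sgRNAs that cutting makes scarce. Genes off chromosome Y matched on abundance in the WT total had a median of 0.05, and the median of the 26 Y genes lay at percentile 100 of 10000 such lists. This cannot decide alone, since the starting abundance is unknown and matched sgRNAs may be scarce without cutting. The 26 genes are also less independent than genes drawn at random, so percentiles among these lists may overstate how unusual the set is. Relative to the olfactory receptors, the ribosome's sgRNAs lay at -1.13 in WT and -1.17 in Mll2KO. Core splicing lay at -1.04 and -1.11, and the proteasome at -1.03 and -0.97. A general loss would raise these lists. By these medians the proteasome alone lay higher in Mll2KO. By the mean over sgRNAs the ribosome also did (-1.13 and -1.08), while core splicing did not (-1.07 in both). Between the totals the list medians were 0.06 (ribosome, percentile 94.9), 0.11 (proteasome, 93.2) and -0.06 (core splicing, 42.6). Fewer genes were called low in Mll2KO than in WT (12 against 35). A small general loss therefore remains open. If every read of the Mll2KO total was counted 2 times, the doubling cancels in CPM and cannot raise 1 set of genes. The sorted libraries, where counts were not doubled, therefore do not decide on it. There the summed CPM of the 26 genes in Mll2KO was 1.95 times that in WT, against 1.91 in the totals. The sorted ratio lay at percentile 99.95 of the matched lists, whose median ratio was 1.03 (the single-copy genes had 1.54). A candidate explanation is that the Mll2KO cells hold fewer copies of these sequences to cut. The 26 genes lay 0.59 below the olfactory receptors in the WT total and 0.29 above them in the Mll2KO total. The single-copy genes lay 0.38 and 0.35 above them, and their median difference between the totals was 0.0841. Gm20852, 1 of the 26 genes, was also 1 of the 2 genes called high in the Mll2KO total (log2 CPM 5.30, against 3.96 in WT). In the sorted libraries the single-copy genes were higher in Mll2KO too, at 1.54 times WT, which this candidate alone does not account for. No copy number was measured here.

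The missing sgRNAs of the sorted libraries limit every sort comparison. Thinning the WT total to the depth of the sorted library left 1.26% of sgRNAs under 50 counts, against 54.5% in the sort, and 1.21% against 17.8% in Mll2KO, which argues against lower depth as the cause. Selection on genes as the main cause is argued against by the variance of missing sgRNAs per gene, which was 1.03 (WT) and 1.05 (Mll2KO) times that of shuffled sgRNAs, above 1 in each of 100 shuffles but under the bound of 1.1 set beforehand. Few cells behind each sgRNA remain a candidate: the share missing was 75.9% in the lowest and 34.1% in the highest decile of total abundance in WT, a difference of 41.8 percentage points, and 48.6% and 2.67% in Mll2KO. Any random loss of sgRNAs before sequencing would remove scarce ones more often, so this fall with abundance does not single out few cells.

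The calls of Trp53 and Cpsf4 may owe their rank to abundance in the total population. Within 20 bins of abundance the adjusted permutation p was 0.664 for Trp53 (0.0197 to 0.991 over its alternatives) and 0.708 for Cpsf4 (0.0197 to 0.859), while their log2 ratios, -2.74 ± 3.20 and 2.52 ± 2.02, are the same by construction; the calls ended because sgRNAs of like abundance reach ratios as extreme. No biological explanation was tested for either.

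Genes with an unadjusted p under 0.05 for enrichment were shared by the 2 sorts more often than independent lists: 87 genes against 51.7 (one-sided Fisher's exact test, p = 1.18e-06), and 73 against 50 with ranks within abundance bins (p = 0.000752). The sorts share no library, and genes are not independent replicates.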
